A study of Mus musculus with 6 samples.

How the data were processed

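Brain tumours of mice were profiled by single-cell RNA sequencing. Per the labels' protocols, tumour cells of NTv-a;hUBC-CreERT2;Adar1flox/flox mice were injected into the brain, and the mice received 5 daily injections of tamoxifen at 100 mg/kg or vehicle once a tumour was seen by MRI. 2 weeks after treatment began, cells without and with the leukocyte marker CD45 were separated and combined at 1 part to 8 parts. Libraries were made with the 10x Genomics 3′ kit v3.1 and sequenced on a NovaSeq instrument, per the labels' protocols. The titles name 3 Adar1-KO libraries (tamoxifen) and 3 Adar1-WT libraries (vehicle). The labels number the replicates but do not say that each came from a separate animal. The p-values of single genes, class shares and list levels therefore measure the spread between these libraries.

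The deposited matrices hold whole-number UMI counts per gene and cell, with no normalization. Per the submitters' processing notes, Cell Ranger 7.2.0, R 4.3.1 and Seurat 5.0.1 were used with the mm10 build. CellBender, a tool that removes free RNA, is named only in the names of the deposited files, and its settings are not given in the sources used here. Each matrix lists 32285 genes by Ensembl identifier and symbol. Of these, 32158 identifiers were found in the GENCODE M21 annotation of GRCm38, which gave the position of Adar. Genes that share sequence with close copies, such as Ifit3 with Ifit3b and the H2 class I genes, have uncertain individual counts.

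Cells with at least 300 genes, at least 500 UMIs and at most 15% mitochondrial UMIs were kept, which left 12187 of 18478 barcodes. Scrublet removed 21 of them (0.17%), a share too low for the caller to have worked, so doublets largely remain. An alternative chosen after seeing the data therefore removed the cells with the highest doublet scores at 0.8% per 1000 barcodes of a library. The 12166 remaining cells were scaled to 10000 counts, log-transformed and grouped in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9) from 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Interferon, MHC, cell cycle, immediate early, mitochondrial, ribosomal and sex-linked genes were left out of the variable genes so that clusters did not rest on the compared response. A cluster took a name when at least 3 fixed markers of a class were each detected in at least 10% of its cells, the marker score exceeded 1 and its 10 leading genes did not favour another class. Of the 35 clusters, 3 stayed unnamed and held 1054 cells (8.7%). These were cluster 4 (led by Ifitm1, S100a4 and Napsa), cluster 26 (led by Ms4a7 and Pf4) and cluster 29 (few UMIs).

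Raw counts were summed per library and class, and sums of fewer than 20 cells were left out. Each class was tested with edgeR 4.0.16 (R 4.3.3), using TMM normalization, filterByExpr and the quasi-likelihood F-test, with Benjamini-Hochberg adjustment at 0.05 and no covariate. Fold changes are libraries labelled Adar1-KO over libraries labelled Adar1-WT. Levels are given as TMM-scaled CPM, computed here from the deposited counts. Genes with few UMIs carry wide errors. The standard error (SE) of each log2 fold change was taken from the F statistic and can be too narrow for such genes. For Adar in T cell-like cells, with 2 UMIs in WT replicate 2, it was 0.384 at −0.179, while the edgeR unadjusted p was 0.854. Gene lists with at least 5 tested members were tested with limma 3.58.1 (camera, preset correlation 0.01), again with the correlation estimated from the data, and with fry. At the preset correlation camera treats members as nearly independent of each other. Its p-values then do not measure the spread between libraries. Camera was also run within single clusters of 4 classes that kept at least 2 libraries of 20 or more cells per group and at least 1000 tested genes. For members of a list, p-values were also adjusted over the list alone. The list level of a library is the mean log2 CPM of its tested members. Where groups without overlap are counted, the share that chance gives covers both directions. Members of a list can vary together, so such a count describes the list and is not a test. Unless another tool is named, passing refers to edgeR.

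Class shares were tested by a two-sided exact permutation test on log2 of the share plus 0.5 cell, with Benjamini-Hochberg adjustment over the classes. With 3 libraries against 3 the smallest possible p is 0.1. Immune classes are shares of immune cells and non-immune classes shares of non-immune cells, because the sort set the ratio between them. The 1054 unnamed cells scored best as immune classes and count as immune cells. They were 65 of 277 immune cells in KO replicate 1 and 154 of 2702 in KO replicate 2. Wilson 95% intervals and limits from 3 counts cover counting error only. Differences between classes were tested with limma on the per-library difference of log2 CPM (prior count 2) and, for the interferon list, by exact permutation.

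Lists, markers, tests, the naming of genes and most alternatives were fixed before the data were examined. The lists were type I interferon-stimulated genes, type II interferon response, MHC class I presentation, MHC class II presentation, double-stranded RNA sensing, integrated stress response, apoptosis and necroptosis, cell cycle, inflammatory cytokines and NF-kB targets, chemokines, homeostatic microglia, disease-associated microglia, hypoxia and glycolysis, immunosuppressive myeloid genes, T and NK cytotoxicity and activation, T cell exhaustion, naive and memory T cell, oligodendrocyte lineage, astrocytic and mesenchymal glioma, extracellular matrix and angiogenesis, phagocytosis and complement, dissociation and immediate early genes, mitochondrially encoded genes, and markers of neutrophils, T cells, glioma and OPC, erythroid cells, B cells and myelinating oligodendrocytes. Named genes were Adar, then up to 10 higher and 10 lower genes per class that passed adjusted p at 0.05 without overlap of the groups, then up to 4 passing members of each called list or, where none passed, its 2 members with the highest average level. A member that this rule selects in monocyte/macrophage-like cells is not used here. Genes outside that rule are named as chosen after their values were seen. Lists can share genes. Ifih1, Dhx58, Eif2ak2, Zbp1, Oas1a, Oas2 and Oas3 are in both the type I interferon and the double-stranded RNA sensing list. Calls of these lists are therefore not independent of each other.

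The edgeR, camera and limma steps were checked on simulated data with genes changed by 2-, 4- or 16-fold, the sizes mixed. With 67, 67 and 66 genes changed at these sizes in each class, the edgeR step recovered 68.7% of 4-fold changes among 10803 glioma/OPC-like genes, 61.2% among 11947 microglia-like genes, 88.1% among 7757 monocyte/macrophage-like genes, 79.1% among 5253 T cell-like genes and 7.5% among 5318 pericyte/smooth muscle-like genes. For 2-fold changes the shares were 9%, 13.4%, 11.9%, 6% and 0% in the same order. False calls numbered 7, 4, 4, 7 and 3. For differences between classes both classes were changed. The limma test recovered 28.8% of 132 4-fold differences (glioma/OPC-like against monocyte/macrophage-like, 6745 genes), 15.3% of 131 (glioma/OPC-like against microglia-like, 9044 genes) and 18.3% of 131 (microglia-like against monocyte/macrophage-like, 7632 genes), and 90.2%, 91.6% and 89.3% of 16-fold ones. Camera called the raised list in every class and 0 of 20 random lists. The simulated genes varied independently, so this check does not cover lists whose members vary together. Some lists tested here do so, such as type I interferon genes in monocyte/macrophage-like cells (estimated correlation 0.66).

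Alternatives covered DESeq2 1.42.0 size factors in edgeR, DESeq2's own test, limma-voom with sample quality weights, no low-count filter, a replicate block, sums of at least 50 cells, stricter cell filters, doublets kept, other cluster resolutions, clusters from all variable genes and leaving out each replicate. Chosen after seeing the data were the removal of top-scored doublets, merging of macrophage clusters, and leaving out together KO replicate 1 (798 barcodes) and WT replicate 3. For gene lists and the Adar level, the settings of cells (sums of at least 50 cells, the stricter filter, doublets kept and other clusters) and the runs within single clusters were also added after seeing the data. Figures were drawn with matplotlib 3.10.9.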

Results

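Single-cell transcriptomes were collected from mouse glioblastomas to learn how gene expression in the tumour and its microenvironment changed after deletion of Adar1, the gene of an enzyme that edits adenosine in double-stranded RNA. The tumour cells carried NTv-a, a transgene for an avian virus receptor, a tamoxifen-inducible Cre recombinase and floxed Adar1. Tamoxifen-treated mice gave 3 libraries labelled Adar1-KO (KO-labelled) and vehicle-treated mice 3 libraries labelled Adar1-WT (WT-labelled). KO replicates 1, 2 and 3 held 798, 3885 and 2926 barcodes with 2207728, 19704660 and 24775463 UMIs, and WT replicates 1, 2 and 3 held 3579, 3222 and 4068 barcodes with 12171261, 11872826 and 20605431 UMIs. After filtering, 335, 3011 and 2319 cells remained in the KO-labelled and 1890, 2328 and 2283 in the WT-labelled libraries. Median UMIs per cell ran from 2263 (WT replicate 2) to 7323 (KO replicate 3), and median mitochondrial shares from 1.6% to 3.19%. No pair of libraries shared more than 5 barcodes, and log2 CPM across genes correlated at r = 0.951 to 0.986 between libraries.

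Adar transcripts were detected in all 6 libraries and were not lower in the KO-labelled ones. Adar (ENSMUSG00000027951; GRCm38 chromosome 3, 89715022 to 89753446, plus strand) stood at 65.37 ± 35.17 CPM over all cells of KO-labelled libraries and 51.15 ± 17.43 in WT-labelled ones (SD, n = 3 each; log2 fold change 0.37, SE 0.448, edgeR adjusted p = 1). In glioma/OPC-like cells, the class that should hold the tumour cells, the levels were 66.14 ± 38.37 and 38.85 ± 15.76 (0.83, SE 0.454), resting on 12 to 83 Adar UMIs per library. Microglia-like cells gave 73.15 ± 32.32 and 50.04 ± 13.89 (0.62, SE 0.346), and monocyte/macrophage-like cells 75.1 ± 37.81 and 52.8 ± 15.84 (0.60). T cell-like cells gave 71.57 ± 27.52 and 77.65 ± 22.32 (−0.18, SE 0.384). In pericyte/smooth muscle-like cells the levels were 61.12 ± 28.98 and 35.65 ± 15.13 (SD, n = 2 each; 0.88, SE 0.618). None of these differences passed the test, and the sign turned without KO replicate 3 over all cells (−0.10) and without KO replicate 1 in T cell-like cells (0.07). Without KO replicate 3 the difference was also smaller in glioma/OPC-like (0.20), microglia-like (0.22) and monocyte/macrophage-like cells (0.31). The labels do not name the floxed exons, and counts taken at the 3′ end may lie outside the deleted part, so the level does not check the labels.

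**Figure D1:**
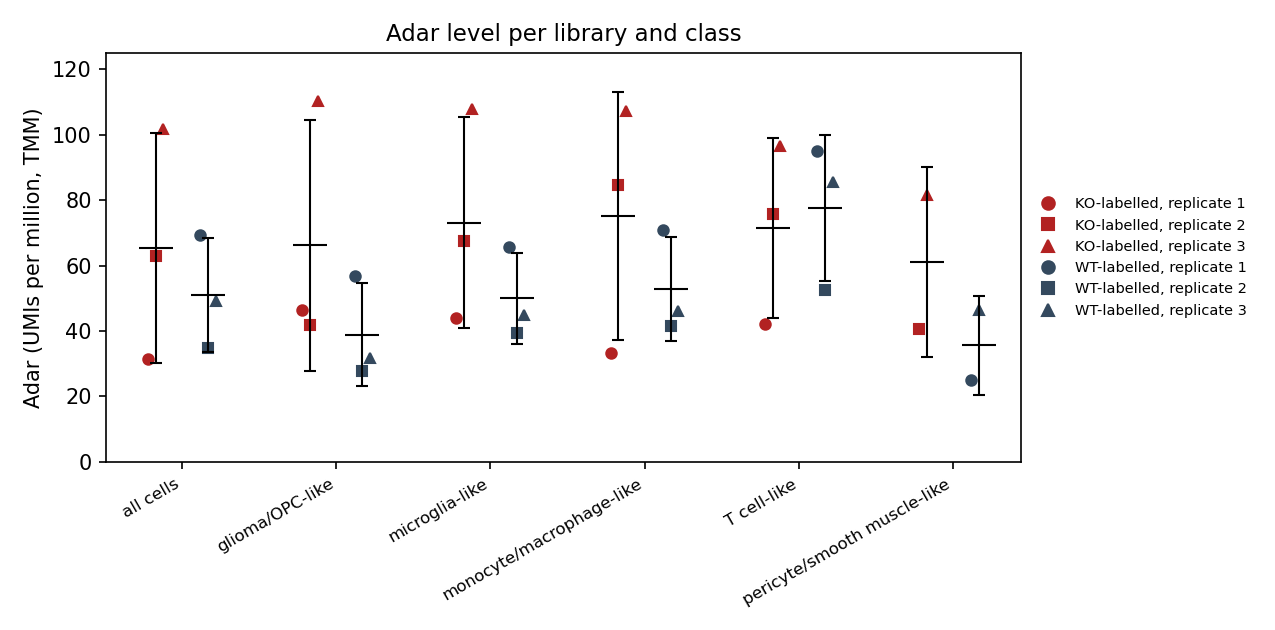
Adar level in CPM (TMM-scaled) on the vertical axis for each library (points) in all cells and in 5 cell classes, with the mean (wide bar) and SD (error bar) of each group. KO replicate 3 had the highest level in all cells (101.7) and KO replicate 1 the lowest (31.5).

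Named clusters fell into 14 classes, of which microglia-like cells were the most numerous (5758 cells), followed by monocyte/macrophage-like (1805), T cell-like (1071) and glioma/OPC-like cells (774). Glioma/OPC-like cells, which express Lhfpl3, Ptprz1 and Olig1, made up 47.98% ± 7.59 of non-immune cells in KO-labelled libraries and 72.86% ± 14.04 in WT-labelled ones (SD, n = 3 each). The groups did not overlap (44.8%, 56.6% and 42.5% against 58.6%, 73.3% and 86.7%), and the exact permutation p of 0.1 is the smallest possible with 3 against 3 (adjusted p = 0.56). T cell-like cells made up 18.9% ± 12.92 of immune cells against 6.19% ± 7.66 (SD, n = 3 each; exact permutation p = 0.2), with KO replicate 2 at 4.0% and WT replicate 1 at 15%. Microglia-like cells, at 43.67% ± 30.96 and 49.34% ± 32.16 of immune cells, and monocyte/macrophage-like cells, at 14.19% ± 12.42 and 17.85% ± 20.69, differed by less than the spread between libraries.

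Smaller classes also failed the test. Oligodendrocyte-like cells made up 20.06% ± 6.37 and 10.33% ± 7.52 of non-immune cells in KO-labelled and WT-labelled libraries, endothelial cell-like cells 9.58% ± 5.45 and 4.89% ± 2.48, and pericyte/smooth muscle-like cells 12.08% ± 6.75 and 11.68% ± 8.9 (SD, n = 3 each). Neuron-like cells (17 cells in all; 4.45% ± 3.5 and 0.11% ± 0.2) did not overlap between the groups (exact permutation p = 0.1, adjusted p = 0.56), and astrocyte-like cells numbered 16. Among immune cells, NK cell-like cells were 3.85% ± 2.64 and 2.49% ± 3.17, border macrophage-like cells 2.8% ± 3.22 and 5.43% ± 5.64, conventional dendritic cell-like cells 2.04% ± 1.58 and 5.41% ± 5.53, and B cell-like cells 0.38% ± 0.12 and 0.69% ± 0.38. Neutrophil-like cells came almost wholly from WT replicate 3 (175 of 182 cells, 8.8% of its immune cells). No share passed, the smallest adjusted p being 0.56, and edgeR on the cell numbers called none either. All shares depend on the sort, and non-immune cells were 6.1% to 17.3% of a library.

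**Figure D2:**
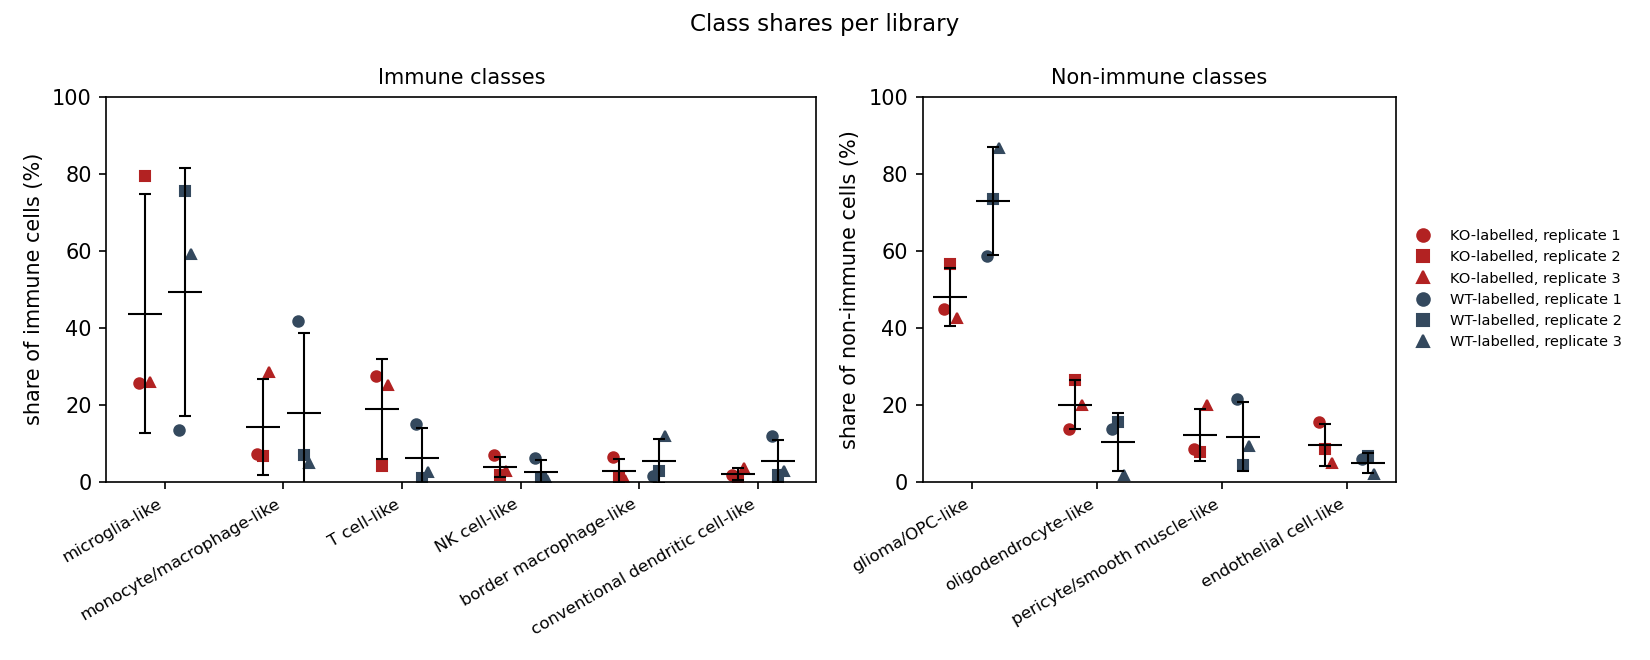
Share of immune cells (left panel) or of non-immune cells (right panel) held by each class, in percent, for each library (points), with the group mean (wide bar) and SD (error bar). Glioma/OPC-like shares were 42.5% to 56.6% in KO-labelled and 58.6% to 86.7% in WT-labelled libraries.

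In monocyte/macrophage-like cells, genes induced by type I interferon, the antiviral cytokine family, were higher as a group in KO-labelled libraries. Of 55 tested members 54 had positive log2 fold changes with a median of 1.07 (camera adjusted p = 2e-29, adjusted p = 0.35 with an estimated correlation). The list level was 7.47 ± 0.73 log2 CPM against 6.53 ± 0.16 (SD, n = 3 each; two-sided exact permutation p = 0.2), with KO replicates 2 and 3 at 7.91 and 7.88 above the WT range of 6.38 to 6.7 and KO replicate 1 at 6.64 inside it. In edgeR no member passed over all genes, and 41 passed adjusted over the list alone. Groups did not overlap for 19, all higher, where chance gives 10% of genes in both directions together. Ifitm3, which blocks viral entry, stood at 1699 ± 494 CPM against 867 ± 348 (0.98, SE 0.38, adjusted p = 0.3), and Ly6e at 1684 ± 483 against 822 ± 300 (1.04, SE 0.38). Among members chosen after their values were seen, Irf7, a transcription factor of the interferon response, was at 552 ± 51.4 against 180 ± 39.8 (1.63, SE 0.27, adjusted p = 0.0834), Oas3, a sensor of double-stranded RNA, at 124 ± 48.3 against 34.4 ± 1.56 (1.93, SE 0.32) and Phf11d at 136 ± 48.5 against 36.3 ± 10.3 (1.94). Ifit3 (2.24) and its near-identical copy Ifit3b (2.61, adjusted p = 0.0569) lay in the same direction. DESeq2 and limma-voom with sample quality weights called Irf7, Oas3, Phf11d, Ifit3 and Ifit3b over all genes.

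Antigen presentation by MHC class I was also higher as a group in these cells, with a median of 1.04 over 20 genes, 11 without overlap and 8 passing adjusted over the list alone (camera adjusted p = 6.24e-11, adjusted p = 0.35 with an estimated correlation). B2m, the light chain of MHC class I, stood at 4224 ± 225 against 2288 ± 1014 CPM (0.88, SE 0.42), and H2-D1, a heavy chain, at 2416 ± 363 against 1053 ± 452 (1.20, SE 0.38, adjusted p = 0.199). All 22 type II interferon response genes were positive with a median of 0.55, 4 passing adjusted over the list alone (camera adjusted p = 7.47e-07, adjusted p = 0.35 with an estimated correlation). Cxcl10, a T cell attractant, was at 669 ± 189 against 299 ± 69.8 (1.17, SE 0.31) and Psme1 at 389 ± 18 against 261 ± 94.6 (0.57, SE 0.31). Double-stranded RNA sensing genes had a median of 0.61 over 19 members, 6 passing adjusted over the list alone (camera adjusted p = 0.00149, adjusted p = 0.36 with an estimated correlation). Ifih1, also a member of the type I interferon list, was at 0.47 (SE 0.38) and Trim25 at 0.25 (SE 0.37). The RNA sensing list shares further genes with the type I list, so it is not separate evidence. In edgeR no gene of these lists passed over all genes. Of the genes named here, DESeq2 called H2-D1 and Cxcl10, and limma-voom with sample quality weights called H2-D1. Leaving out 1 library moved the type II median to 0.85 (KO replicate 2), 0.29 (KO replicate 3) or 1.34 (WT replicate 1) and the RNA sensing median to 0.31 (KO replicate 3) or 0.34 (WT replicate 2), all still called.

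Further lists were called in monocyte/macrophage-like cells at the preset correlation. Dissociation and immediate early genes were higher (22 of 23 positive, median 0.79, 10 without overlap, 7 passing adjusted over the list alone, camera adjusted p = 2.46e-10, adjusted p = 0.35 with an estimated correlation). Junb was at 1596 ± 298 against 1019 ± 294 CPM (0.64, SE 0.34) and Hsp90ab1 at 0.20 (SE 0.31). The 13 mitochondrially encoded genes were all lower (median −0.83, 8 without overlap, 0 passing adjusted over the list alone, camera adjusted p = 1.7e-06, adjusted p = 0.36 with an estimated correlation). The mitochondrial gene mt-Co1 was at 4102 ± 1297 against 7287 ± 1528 (−0.83, SE 0.41) and mt-Co3 at −0.81 (SE 0.42). Integrated stress response genes had a median of 0.73 (11 members; 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.27 with an estimated correlation). Atf3 was at 1.04 (SE 0.36) and Cebpb at 0.28 (SE 0.34). Chemokines had a median of 0.83 (2 of 14 higher adjusted over the list alone; Ccl4 0.84, SE 0.38, and Cxcl2 −0.16, SE 0.55), and homeostatic microglia genes 0.41 (1 of 19; Tgfbr1 0.30, SE 0.26), with adjusted p = 0.27 and adjusted p = 0.42 with an estimated correlation. Apoptosis and necroptosis genes had a median of 0.54 (1 of 16 adjusted over the list alone, adjusted p = 0.36 with an estimated correlation; Cdkn1a 0.80, SE 0.45; Casp4 0.16, SE 0.28). Without KO replicate 1 and WT replicate 3 together, the chemokine (0.53) and homeostatic (0.23) calls ended and the immediate early median was 0.43. The apoptosis call ended without KO replicate 2 (0.10) or KO replicate 3 (0.30). With macrophage clusters merged the mitochondrial call was lost (−0.10), the chemokine median turned to −0.57, and the stress response (0.38), apoptosis (0.30) and immediate early (0.42) medians were smaller, as at Leiden resolution 0.5 (0.35, 0.29 and 0.42). Within clusters 2 and 27, camera called neither the immediate early (0.24 and 0.11), the chemokine (0.44 and 0.23) nor the homeostatic list (0.15 and −0.02). Within cluster 27 the integrated stress response (0.24) and apoptosis lists (0.22) were not called either. The mitochondrial list was called lower within clusters 2 and 27 (−0.92 and −0.39), both without KO replicate 1.

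Lower lists in the same class were extracellular matrix and angiogenesis (5 of 6 members negative, median −0.85; 1 lower adjusted over the list alone, adjusted p = 0.35 with an estimated correlation), astrocytic and mesenchymal glioma genes (12 of 15, −0.71; 1 lower, adjusted p = 0.61 with an estimated correlation) and hypoxia and glycolysis (16 of 20, −0.29; 0 lower, adjusted p = 0.61 with an estimated correlation). Fn1, which encodes fibronectin and is also a naming marker of the class, stood at 4.72 ± 5.63 against 310 ± 355 CPM (−5.80, SE 0.98, adjusted p = 0.0834), and Mmp14 at −0.29 (SE 0.28). Cd44 was at 439 ± 183 against 1025 ± 548 (−1.25, SE 0.43), Apoe at 0.22 (SE 0.58), Hk2, a glycolytic enzyme, at −1.0 (SE 0.39) and Gapdh at −0.39 (SE 0.31). Leaving out 1 library ended the extracellular matrix call (−0.58 without KO replicate 1) or moved it (−1.30 without WT replicate 1). The mesenchymal call ended without KO replicate 1 (−0.47), KO replicate 3 (−0.35), WT replicate 2 (−0.67) or WT replicate 3 (−0.07) and moved without KO replicate 2 (−1.10) or WT replicate 1 (−1.11). The hypoxia call ended without KO replicate 1 (−0.27), KO replicate 3 (−0.23) or WT replicate 3 (−0.11) and moved without KO replicate 2 (−0.46) or WT replicate 1 (−0.48). With the stricter filter, at Leiden resolutions 0.5 and 2 and with macrophages merged the hypoxia medians were −0.77, −0.67, −0.69 and −0.56. Within clusters 2 and 27 camera did not call the mesenchymal list (−0.35 and −0.88, adjusted p = 0.096 and 0.376), and within cluster 2 it did not call hypoxia genes (−0.02, adjusted p = 0.358).

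Single genes did not pass in edgeR in the monocyte/macrophage-like class as a whole. edgeR called 0 of 7757 genes (1056 at an unadjusted p under 0.05, smallest adjusted p 0.0569), DESeq2 called 63 higher and 96 lower, and limma-voom with sample quality weights 156 higher and 185 lower. Without WT replicate 1, edgeR called 2 higher and 13 lower. Within cluster 2 (2 against 2 libraries) it called 7 higher and 14 lower of 9512 genes, and within cluster 27 (2 against 3) 0 of 4870. Outside the lists and chosen after their values were seen, Cited2 stood at 501 ± 140 against 129 ± 33.8 CPM (1.95, SE 0.32), Ahr, a ligand-activated transcription factor, at 20.2 ± 12.3 against 106 ± 25.2 (−2.09, SE 0.35), and Fkbp5 at 221 ± 66.1 against 74.7 ± 21.7 (1.63, SE 0.33, adjusted p = 0.0843). The class was drawn from different clusters in the groups. Cluster 2 (Ly6c2 and MHC class II genes leading, median 14246 UMIs) held 50%, 65.8% and 75.8% of its cells in KO replicates 1, 2 and 3 and 30.8%, 38% and 10.1% in WT replicates 1, 2 and 3, while cluster 27 (median 2433 UMIs) held 35%, 27.7% and 23.1% against 66.5%, 52.8% and 87.9%. KO replicate 1 gave 20 cells of the class.

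In glioma/OPC-like cells, the interferon lists were higher in KO-labelled libraries and the hypoxia list lower at the preset correlation, and each call hung on 1 library. Type I interferon genes had a median of 1.34 (36 of 37 positive, 2 without overlap where chance gives 10%, 0 passing over all genes or adjusted over the list alone, camera adjusted p = 5e-09, adjusted p = 0.74 with an estimated correlation). The list level was 5.92 ± 1.99 log2 CPM against 5.18 ± 0.67 (SD, n = 3 each; exact permutation p = 0.6), with KO replicates 1, 2 and 3 at 3.89, 6.01 and 7.86. Without KO replicate 3 the median was 0.08 and the call ended. Within clusters 1 and 5, both without KO replicate 1, the list was called (1.55, and 2.58 over 9 members). Isg15, a ubiquitin-like antiviral protein, was at 526 ± 665 against 171 ± 115 CPM (1.65, SE 1.0), and Ifitm3 at 366 ± 392 against 261 ± 99.6 (0.51, SE 0.88). Type II genes were all positive (17 genes, median 2.64, 0 adjusted over the list alone, camera adjusted p = 1.58e-08, adjusted p = 0.73 with an estimated correlation). Cxcl10 was at 929 ± 1431 against 66.3 ± 104 (3.75, SE 1.8) and Irgm1 at 0.84 (SE 0.5). The call ended without KO replicate 3 (0.33). Hypoxia and glycolysis genes were negative in 21 of 22 cases (median −1.01, 6 without overlap, 0 adjusted over the list alone, camera adjusted p = 5.34e-08, adjusted p = 0.73 with an estimated correlation). Mif was at 479 ± 115 against 740 ± 359 (−0.64, SE 0.39) and Gapdh at 335 ± 41.7 against 599 ± 509 (−0.85, SE 0.55). This hypoxia call ended without WT replicate 3 (−0.36), whose list level of 7.43 was the highest.

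Transcripts usual in myeloid cells also differed in the glioma/OPC-like class. Phagocytosis and complement genes had a median of 2.67 (6 of 8 higher adjusted over the list alone, camera adjusted p = 3.75e-07, adjusted p = 0.56 with an estimated correlation), with levels of 3.74, 5.54 and 7.13 in KO replicates 1, 2 and 3 and 4.18 to 4.35 in the WT-labelled libraries, and 0.98 without KO replicate 3. C1qa, a complement subunit made by microglia, was at 94.5 ± 115 against 14.8 ± 6.41 CPM (2.81, SE 0.84), and Lamp1 at −0.20 (SE 0.31). The list changed sign under other cell settings (−0.43 with clusters from all variable genes, −0.07 with doublets kept). Immunosuppressive myeloid genes had a median of 1.5 over 5 members (2 adjusted over the list alone, adjusted p = 0.56 with an estimated correlation), moving to 0.90 without KO replicate 1, 0.89 without WT replicate 1 and −0.08, no longer called, without KO replicate 3. Still called, the median was −0.05 with the stricter cell filter, which leaves KO replicate 1 out of this class, 2.44 without KO replicate 1 and WT replicate 3 together and 2.38 with top doublets removed. Its best-detected members lay the other way: Lgals1 at −0.64 (SE 0.52) and Hmox1 at −1.59 (SE 1.1).

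Further lists were called in glioma/OPC-like cells, and each of these calls ended with the omission of at least 1 library. Integrated stress response genes had a median of 0.49 (0 of 20 adjusted over the list alone, adjusted p = 0.74 with an estimated correlation; Atf4 0.13, SE 0.33; Nupr1 −2.17, SE 1.01). This call ended without KO replicate 2 (0.45), KO replicate 3 (0.17), WT replicate 1 (0.43) or WT replicate 2 (0.40). The median was larger without KO replicate 1 (0.74), WT replicate 3 (0.87) or both (1.04), and with the stricter filter (0.76). Oligodendrocyte lineage genes had a median of 0.15 (0 of 20, adjusted p = 0.73 with an estimated correlation; Lhfpl3 −0.06, SE 0.36; Ptprz1 0.24, SE 0.36). That call was absent without KO replicate 1 (0.18), KO replicate 3 (0.11), WT replicate 2 (0.20) or WT replicate 3 (0.06), and the median was 0.31 and 0.58 without KO replicate 2 and WT replicate 1. Mitochondrially encoded genes were at 0.37 (13 of 13 positive, 0 adjusted over the list alone, adjusted p = 0.74 with an estimated correlation; mt-Atp6 0.45, SE 0.34; mt-Co3 0.56, SE 0.32). The mitochondrial call was lost without KO replicate 1 (0.17), WT replicate 1 (0.36) or WT replicate 3 (0.35), and the median was 0.67 without KO replicate 3. Astrocytic and mesenchymal genes were at −0.71 (1 of 19 higher adjusted over the list alone, adjusted p = 0.83 with an estimated correlation; Apoe −0.34, SE 0.56; Vim −0.71, SE 0.52). No call was made without KO replicate 1 (−0.57), KO replicate 2 (−0.93), WT replicate 2 (−0.65) or WT replicate 3 (−0.36), and the median was −1.15 without WT replicate 1. Extracellular matrix genes were at −0.54 (1 of 10 lower adjusted over the list alone, adjusted p = 0.56 with an estimated correlation; Sparc −0.48, SE 0.44; Postn −0.14, SE 0.43). Leaving out WT replicate 3 ended the call (−0.47), and the median was −1.02 and −1.08 without KO replicate 3 and WT replicate 1. Within clusters 1 and 5, camera called neither oligodendrocyte lineage (0.13 and 0.26), mesenchymal (−0.56 and −0.23) nor mitochondrially encoded genes (0.11 and −0.39), and extracellular matrix genes, tested in cluster 1 alone, were not called there (−0.31). edgeR called 0 of 10803 genes (488 at an unadjusted p under 0.05), and 5 higher and 2 lower of 1387 within cluster 5 and 0 of 9258 within cluster 1 (2 against 3 libraries each). DESeq2 called 13 higher and 3 lower, and limma-voom with sample quality weights 0. The class held 26 cells in KO replicate 1 and 62 in KO replicate 3, and its main clusters differed by library, cluster 5 (median 1080.5 UMIs) holding 59.1% in WT replicate 3 and cluster 1 (9495 UMIs) 70.9% in KO replicate 2.

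In microglia-like cells, cell cycle genes were lower as a group in KO-labelled libraries and hypoxia genes were lower, while interferon and MHC genes were higher, all at the preset correlation. Of 47 cell cycle genes 46 had negative log2 fold changes (median −0.72, 12 without overlap where chance gives 10%, 0 passing over all genes or adjusted over the list alone, camera adjusted p = 4e-14, adjusted p = 0.74 with an estimated correlation). Their level was 2.39 ± 1.08 log2 CPM against 3.79 ± 0.14 (SD, n = 3 each; exact permutation p = 0.1, the smallest possible), and the median was −1.89 without KO replicate 2. KO replicates 1, 2 and 3 stood at 1.58, 3.61 and 1.99 and WT replicates 1, 2 and 3 at 3.89, 3.63 and 3.85. KO replicate 2, with 2146 cells of the class, thus lay just under WT replicate 2. KO replicate 1 had 71 cells and 358533 UMIs, so many of these genes can rest on few or no UMIs there. Such genes lower a mean of log2 CPM, so its level may partly reflect low counts. KO replicate 3 had 3547122 UMIs in the class. H2afz stood at 251 ± 98.3 against 412 ± 38.8 CPM (−0.72, SE 0.32, adjusted p = 0.56) and Tubb5 at 147 ± 40.5 against 218 ± 45.5 (−0.56, SE 0.29). Hypoxia and glycolysis genes had a median of −1.15 (20 of 24 negative, 8 lower and 1 higher adjusted over the list alone, camera adjusted p = 4.21e-06, adjusted p = 0.74 with an estimated correlation), and −0.47 without WT replicate 3, whose level was the highest (6.59). Hypoxia genes were at −0.44 without KO replicate 1 and WT replicate 3 together, and were not called within cluster 20 (−0.23). Mif, a cytokine induced by hypoxia, was at 176 ± 67 against 607 ± 426 (−1.77, SE 0.49), and Gapdh at 389 ± 155 against 996 ± 825 (−1.35, SE 0.54).

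Interferon and antigen presentation lists were higher in microglia-like cells at the preset correlation. Type I interferon genes had a median of 0.49 (45 of 56 positive, 2 without overlap higher and 1 lower, 0 adjusted over the list alone, camera adjusted p = 0.000754, adjusted p = 0.74 with an estimated correlation), with KO replicates 1, 2 and 3 at 5.07, 6.55 and 7.04 and WT replicates at 6.43, 5.37 and 6.06. Ly6e was at 0.22 (SE 0.33) and Ifi27l2a at −0.75 (SE 0.38). The call ended without KO replicate 3 (0.06) or WT replicate 2 (0.24), and the median was 0.79 without KO replicate 1 and also without WT replicate 1, and 0.86 without KO replicate 1 and WT replicate 3 together. Within clusters 3, 16 and 20, each without KO replicate 1, the type I list was called (0.93, 0.88 and 1.06). Type II genes had a median of 0.92 (3 of 22 adjusted over the list alone, adjusted p = 0.74 with an estimated correlation; Cxcl10 0.04, SE 0.44; Icam1 0.55, SE 0.31). Their call ended without KO replicate 3 (−0.10) or WT replicate 2 (0.65). MHC class I genes had a median of 0.67 (0 of 20 adjusted over the list alone, 4 without overlap higher, adjusted p = 0.74 with an estimated correlation). H2-D1 was at 2204 ± 685 against 1212 ± 164 CPM (0.86, SE 0.3), B2m at 0.03 (SE 0.28), and the call ended without KO replicate 3 (0.21). MHC class II genes, which present antigen to helper T cells, had a median of 0.81 (0 of 13 adjusted over the list alone, adjusted p = 0.74 with an estimated correlation). Cd74 was at 1992 ± 2820 against 454 ± 547 (2.14, SE 1.23) and Ctss at 0.10 (SE 0.27). Their call ended without KO replicate 3 (−0.21) or WT replicate 2 (0.91), and the median was 1.23 without KO replicate 2. The MHC class II call was also lost with the replicate block (0.26), with clusters from all variable genes (0.82) and at Leiden resolution 2 (0.70). Double-stranded RNA sensing genes were at 0.45 (0 of 19 adjusted over the list alone, adjusted p = 0.74 with an estimated correlation; Ifih1 0.54, SE 0.54; Eif2ak2 0.55, SE 0.55, both also in the type I interferon list). The call was lost without KO replicate 3 (0.18) or WT replicate 2 (0.32), and within cluster 16 (0.60).

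Disease-associated microglia genes, an activation programme, had a median of −0.82 in microglia-like cells (20 of 23 negative, 0 adjusted over the list alone, camera adjusted p = 0.000429, adjusted p = 0.74 with an estimated correlation), while Apoe was at −0.03 (SE 0.64) and Ctsd at −0.41 (SE 0.4). The call ended without KO replicate 1 (−0.65), and the median was −0.23 without WT replicate 3. Without both of these libraries the median was 0.01 and the list was not called. Within clusters 3, 16 and 20 it was not called either, with medians of −0.50, 0.11 and −0.43, and nor were the chemokines below. Chemokines had a median of −0.69 (1 of 16 lower adjusted over the list alone, adjusted p = 0.74 with an estimated correlation). Ccl4 was at 2175 ± 1047 against 3437 ± 974 CPM (−0.66, SE 0.38) and Ccl5 at 0.76 (SE 1.22). The chemokine call ended without WT replicate 3 (−0.54), and the median was −1.24 without KO replicate 2. Extracellular matrix genes were at −1.04 (0 of 11 adjusted over the list alone, adjusted p = 0.74 with an estimated correlation; Fn1 −6.02, SE 1.82; Sparc −0.61, SE 0.62) and at −0.64 without WT replicate 2. Immediate early genes were at 0.33 (0 of 23, adjusted p = 0.74 with an estimated correlation; Junb 0.21, SE 0.31; Hsp90ab1 −0.51, SE 0.28). This call was lost without KO replicate 1 (0.19), KO replicate 2 (0.05), WT replicate 1 (0.26) or WT replicate 2 (0.31), and within clusters 3 and 16 (0.11 and 0.31), and within cluster 20 camera called the list in the opposite direction, with a median of −0.64 (1 of 20 members positive, adjusted p = 0.0162). edgeR called 0 of 11947 genes (1059 at an unadjusted p under 0.05). DESeq2 called 20 higher and 12 lower, and limma-voom with sample quality weights 0. Chosen after their values were seen, Ccnd3, a G1 cyclin, stood at 300 ± 53.9 against 82.7 ± 23.6 (1.86, SE 0.3, adjusted p = 0.511) and Fkbp5 at 214 ± 29.6 against 84.4 ± 14.2 (1.33, SE 0.26). Clusters of the class differed by library. Cluster 20, whose leading genes include the interferon-induced Oasl1, held 55% of the class in KO replicate 3 and 44.1% in WT replicate 1, and cluster 33, led by Hmox1 and Spp1, held 16.4% in WT replicate 3 and at most 0.4% elsewhere.

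**Figure D3:**
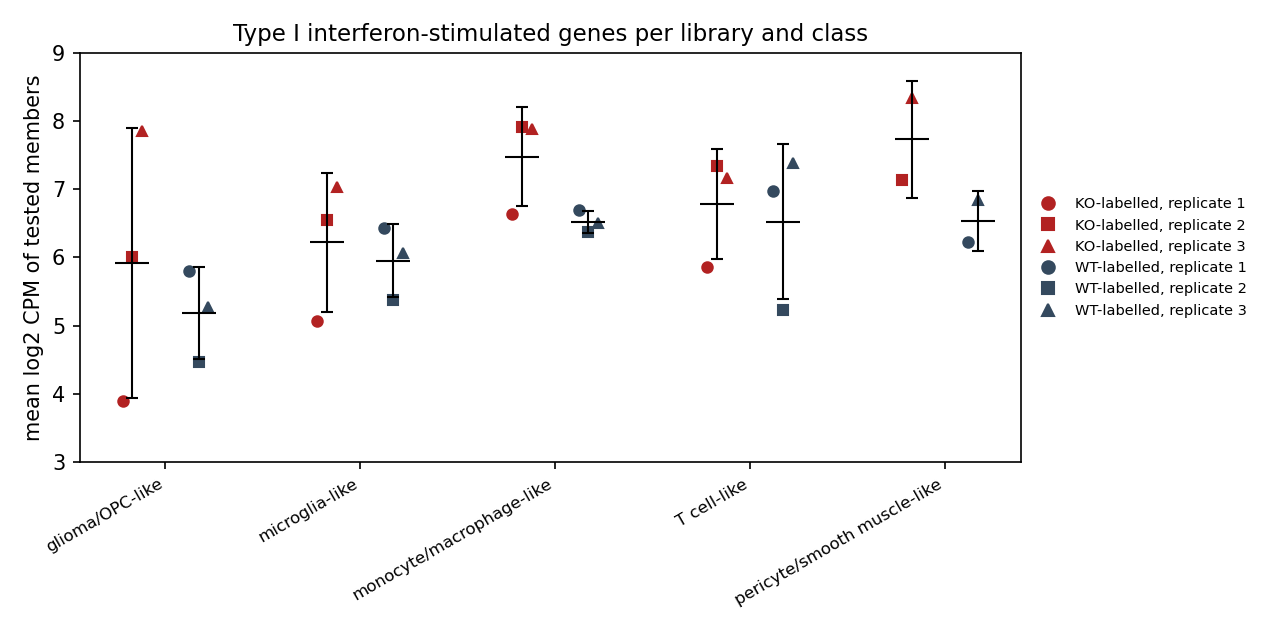
Mean log2 CPM of the tested type I interferon-stimulated genes (vertical axis) for each library (points) in 5 cell classes, with the group mean (wide bar) and SD (error bar); the axis starts at 3. In monocyte/macrophage-like cells KO replicates 2 and 3 lay at 7.91 and 7.88 and the WT-labelled libraries at 6.38 to 6.7.

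In T cell-like cells, genes of naive and memory T cells were lower as a group in KO-labelled libraries and cell cycle and exhaustion genes were higher, at the preset correlation. The naive and memory list had a median of −1.42 (8 of 11 negative, 4 without overlap where chance gives 10%, 4 lower adjusted over the list alone, camera adjusted p = 4.18e-10, adjusted p = 0.41 with an estimated correlation), and −0.94 without KO replicate 3 and −0.78 without KO replicate 1 and WT replicate 3 together. Bach2, a repressor that restrains effector differentiation, stood at 252 ± 74.8 against 671 ± 262 CPM (−1.42, SE 0.37, adjusted p = 1), and Il7r at 505 ± 357 against 422 ± 96. Chosen after their values were seen, Tcf7, a factor of memory-like T cells, was at 47.3 ± 22.7 against 179 ± 91.5 (−1.92, SE 0.57) and S1pr1, a receptor for exit from tissue, at 19 ± 23.4 against 163 ± 81.4 (−3.0, SE 0.74). Cell cycle genes had a median of 0.92 (21 of 22 positive, 0 adjusted over the list alone, adjusted p = 0.51 with an estimated correlation; Hmgb2 0.47, SE 0.43; H2afz 0.66, SE 0.34). No call remained without KO replicate 3 (0.63) or WT replicate 3 (0.61), and the median was 1.67 without WT replicate 1. Exhaustion genes had a median of 0.55 (13 of 15 positive, 0 adjusted over the list alone, adjusted p = 0.41 with an estimated correlation; Tox 0.30, SE 0.45; Ctla4 0.12, SE 0.42). Leaving out KO replicate 3 ended the call (0.07). Within cluster 17, the T cell cluster in which all 6 libraries could be tested, the medians were −0.95 for naive and memory, 0.53 for exhaustion and 0.16 for cell cycle genes, and camera did not call the cell cycle list (adjusted p = 0.676).

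Type I interferon genes were not called in T cell-like cells, with a median of 0.01. The list was called without KO replicate 1 (median 0.30), WT replicate 2 (−0.12) or WT replicate 3 (0.20). MHC class I genes were at 0.32 (0 of 20 adjusted over the list alone, adjusted p = 0.53 with an estimated correlation; H2-K1 0.40, SE 0.32; B2m 0.37, SE 0.35). The call ended with the omission of KO replicate 2 (0.29), KO replicate 3 (0.14), WT replicate 1 (0.27) or WT replicate 2 (0.24), and the median was 0.64 without WT replicate 3. Of the list named for astrocytic and mesenchymal glioma, 9 of 10 members detected in T cell-like cells were positive (median 0.58, 1 adjusted over the list alone, adjusted p = 0.41 with an estimated correlation). S100a6, a calcium-binding protein also made by activated T cells, was at 879 ± 264 against 472 ± 134 CPM (0.88, SE 0.36), and Apoe at 0.40 (SE 1.44). That call ended without KO replicate 2 (0.39) or WT replicate 1 (0.30), and the median was 0.87 without KO replicate 1. Without KO replicate 1 and WT replicate 3 together the MHC class I and mesenchymal medians were 0.70 and 1.19. Immediate early genes were at 0.54 (0 of 19 adjusted over the list alone, adjusted p = 0.53 with an estimated correlation; Junb 0.74, SE 0.44; Hsp90ab1 0.34, SE 0.35). The call ended without KO replicate 1 (0.23), KO replicate 2 (0.56) or WT replicate 1 (0.10). The median was 0.86 and 0.89 without KO replicate 3 and WT replicate 3. Within cluster 17 camera called neither MHC class I (0.16), mesenchymal (0.16) nor immediate early genes (0.07), each at adjusted p = 0.716. edgeR called 0 of 5253 genes (159 at an unadjusted p under 0.05), and DESeq2 and limma-voom with sample quality weights called 0. The class was made of different cells in each library. Cluster 15, led by Cd8a and Nkg7, held 43.6% of it in KO replicate 3 and 0% to 6.8% elsewhere. Cluster 14, led by Il23r and Trdc, held 42.1% in KO replicate 1, and cluster 17 29% to 91.3%, with 23 cells of the class in WT replicate 2.

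Pericyte/smooth muscle-like cells reached the minimum number of cells in KO replicates 2 and 3 and WT replicates 1 and 3. The 10 leading genes of their cluster held 2 markers of the class (Vtn and Rgs5) and 2 of fibroblasts (Dcn and Col3a1), so the class may also hold fibroblasts. Type I interferon genes had a median of 1.23 there (44 of 46 positive, 24 without overlap where chance gives 33.3% of genes with 2 against 2, 0 adjusted over the list alone, camera adjusted p = 7.61e-16, adjusted p = 0.49 with an estimated correlation), and 0.34 without KO replicate 3. Isg15 was at 1211 ± 871 against 592 ± 299 CPM (SD, n = 2 each; 1.04, SE 0.75) and Ifitm3 at 0.16 (SE 0.58). MHC class I genes were at 0.87 (7 of 18 without overlap, 0 adjusted over the list alone, adjusted p = 0.51 with an estimated correlation; H2-D1 2.43, SE 0.74; B2m 0.82, SE 0.69), RNA sensing genes at 0.87 (2 of 13 adjusted over the list alone, adjusted p = 0.49 with an estimated correlation; Ifih1 1.47, SE 0.55; Eif2ak2 0.65, SE 0.49) and type II genes at 1.21 (0 of 19, adjusted p = 0.59 with an estimated correlation; Iigp1 2.00, SE 1.1; Cxcl10 1.22, SE 1.11). All 3 calls ended without KO replicate 3 (0.03, 0.34 and −0.63), the type II call also without WT replicate 1 (1.44), and without KO replicate 2 the medians were 1.39, 1.36 and 2.24. Each omission leaves 1 library in a group, which is then assumed to vary like the other group. The RNA sensing genes Ifih1 and Eif2ak2 are also members of the type I interferon list.

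Lower in pericyte/smooth muscle-like cells at the preset correlation were cell cycle genes (12 of 13 negative, median −1.27, 1 adjusted over the list alone, adjusted p = 0.49 with an estimated correlation; Tubb5 −1.10, SE 0.51; H2afz −1.27, SE 0.61), astrocytic and mesenchymal genes (13 of 17, −1.47, 0 adjusted over the list alone, adjusted p = 0.49 with an estimated correlation), extracellular matrix genes (13 of 16, −0.65, 0, adjusted p = 0.49 with an estimated correlation) and hypoxia genes (14 of 16, −1.17, 0, adjusted p = 0.51 with an estimated correlation). Lgals1 stood at 953 ± 261 against 3471 ± 1777 CPM (SD, n = 2 each; −1.86, SE 0.63), Spp1 at −1.47 (SE 1.19), Sparc at 1900 ± 53.5 against 3163 ± 1054 (−0.74, SE 0.54), Col4a1 at −0.66 (SE 0.58), Mif at 152 ± 33.3 against 832 ± 891 (−2.45, SE 0.99) and Gapdh at −1.26 (SE 0.87). Mitochondrially encoded genes were at −0.49 (11 of 13 negative, 0 adjusted over the list alone, adjusted p = 0.51 with an estimated correlation; mt-Atp6 −0.33, SE 0.55; mt-Co3 0.03, SE 0.54), and immediate early genes at 0.57 (19 of 23 positive, 0, adjusted p = 0.49 with an estimated correlation; Fos 0.57, SE 0.51; Hsp90ab1 −0.55, SE 0.51). The cell cycle median was −6.30 without KO replicate 2, −3.10 without WT replicate 3 and −2.17 with the stricter filter, and the extracellular matrix median −1.38, −1.87 and −1.05 without KO replicate 2, KO replicate 3 and WT replicate 1. Without WT replicate 3 the hypoxia call ended (0.22) and the mesenchymal median was −0.77, and without WT replicate 1 the hypoxia median was −1.78. The immediate early call ended without KO replicate 2 (0.75), KO replicate 3 (0.10) or WT replicate 1 (0.64), and the mitochondrial call without KO replicate 3 (−0.32), WT replicate 1 (−0.57) or WT replicate 3 (−0.43), with −0.79 without KO replicate 2. edgeR called 0 of 5318 genes (232 at an unadjusted p under 0.05). DESeq2 called 6 higher and 5 lower, and limma-voom with sample quality weights 0. Without KO replicate 3 edgeR called 28 higher and 58 lower, and without KO replicate 2 15 higher and 8 lower.

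**Figure D4:**
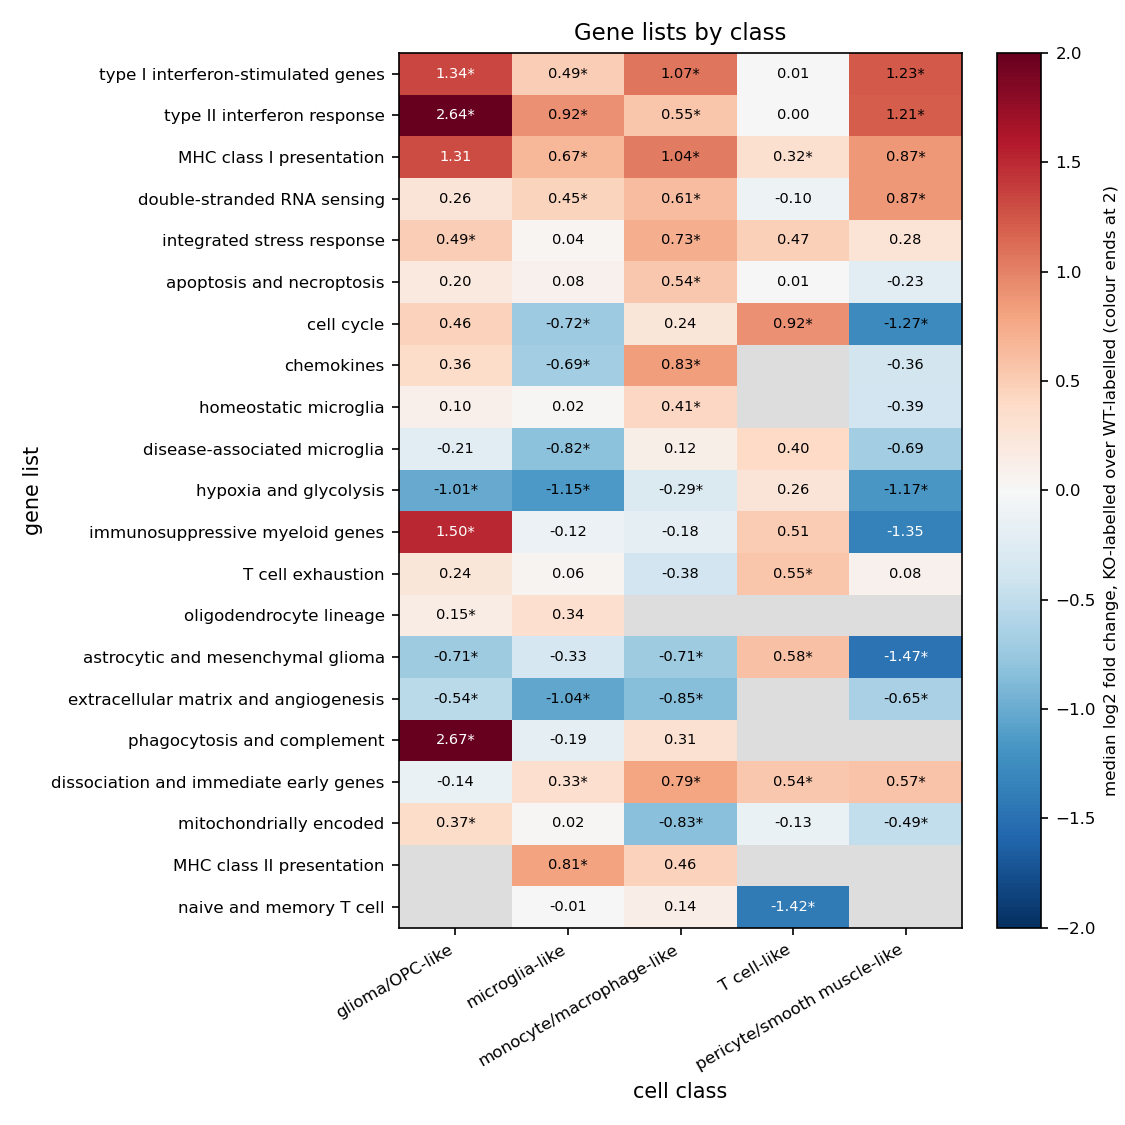
Median log2 fold change (colour and number) of each gene list (vertical axis) in each of 5 cell classes (horizontal axis); stars mark lists called by camera at the preset correlation, and grey marks lists with fewer than 5 tested members. Type I interferon genes had medians of 1.34, 0.49, 1.07, 0.01 and 1.23 from left to right, and no starred call held with an estimated correlation.

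Several lists were called in none of the classes where they were tested. Inflammatory cytokines and NF-kB targets had medians of −0.18 to 0.38 over 5 classes (smallest camera adjusted p = 0.109). T and NK cytotoxicity and activation genes had a median of −0.01 and T cell markers 0.18 in T cell-like cells (adjusted p = 0.887 and 0.0798), and glioma and OPC markers a median of 0.09 in glioma/OPC-like cells (adjusted p = 0.162). Markers of neutrophils, erythroid cells, B cells and myelinating oligodendrocytes had fewer than 5 tested members in each of the classes.

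Whether the response differed between classes was tested within libraries. limma called 0 genes for glioma/OPC-like against monocyte/macrophage-like, glioma/OPC-like against microglia-like and microglia-like against monocyte/macrophage-like cells, with 452, 450 and 693 genes at an unadjusted p under 0.05 and smallest adjusted p of 0.086, 0.803 and 0.526. Type I interferon genes stood lower in microglia-like than in monocyte/macrophage-like cells by −1.09 ± 0.32 log2 CPM in KO-labelled and −0.5 ± 0.35 in WT-labelled libraries (SD, n = 3 each), a difference of −0.59 (exact permutation p = 0.2). For glioma/OPC-like against monocyte/macrophage-like cells the difference was −0.24 (exact permutation p = 0.9), turning to 0.44 without KO replicate 1, and for glioma/OPC-like against microglia-like cells 0.48 (exact permutation p = 0.7), turning to −0.05 without KO replicate 3. Without KO replicate 3 limma called 1 gene for glioma/OPC-like against monocyte/macrophage-like cells.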

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

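Each result was recomputed under other settings, and the cause of a change was not tested. Some settings change 2 things. The stricter cell filter changes the gene and the mitochondrial limit together and takes KO replicate 1 out of glioma/OPC-like and monocyte/macrophage-like cells and WT replicate 2 out of T cell-like cells (under 20 cells). Leiden resolution 2 takes KO replicate 1 out of monocyte/macrophage-like cells, and a further setting leaves out a pair of libraries. Over 3455 alternatives of 200 results, 3077 gave the same outcome, 209 lost a call, 62 gained one, 32 moved and 75 changed sign. Very small values were given no direction, so turns of sign to or from such values are not among the 75. One such turn was oligodendrocyte lineage genes in glioma/OPC-like cells, from 0.15 to −0.02 with top doublets removed. Only lists had calls to lose, because no gene, share or difference between classes passed in the main setting. For those results the same outcome meant that there was still no call and no change of sign. Of 863 alternatives of list medians, 638 gave the same outcome and 209 lost a call, where the median could be unchanged or larger. Settings that left the same libraries in a class were counted separately. Among named genes, 28 of 113 changed sign somewhere. Leaving out both doubted libraries (KO replicate 1 and WT replicate 3), removing top-scored doublets and merging macrophage clusters were chosen after the data were seen, as were, for lists and Adar, the other settings of cells. Limits are the confounding of tamoxifen with the Adar1-KO label, the 3 libraries per group and the dependence of list calls on the preset correlation and, in several classes, on KO replicate 3. Leaving out a pericyte/smooth muscle-like library leaves 1 in its group, which is assumed to vary like the others.

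Genes called with no low-count filter numbered 237 (glioma/OPC-like), 186 (microglia-like), 499 (monocyte/macrophage-like), 64 (T cell-like) and 122 (pericyte/smooth muscle-like). DESeq2 called 16, 32, 159 and 11 in these classes apart from T cell-like cells, and limma-voom with sample quality weights called 341 in monocyte/macrophage-like cells. Removing top doublets gave 2 genes there, and leaving out both doubted libraries gave 1 in T cell-like cells. Leave-one-out counts ran from 0 to 15 in monocyte/macrophage-like and from 0 to 86 in pericyte/smooth muscle-like cells, and from 0 to 1 for the difference between glioma/OPC-like and monocyte/macrophage-like cells.

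With an estimated correlation, and with fry's directional test, 0 lists were called in each of the 5 classes. The type I interferon medians stayed at 1.34 (glioma/OPC-like), 0.49 (microglia-like), 1.07 (monocyte/macrophage-like) and 1.23 (pericyte/smooth muscle-like). Fry's mixed test, which counts changes in either direction, passed for several lists. Examples were chemokines in monocyte/macrophage-like cells (fry mixed adjusted p = 0.0065), exhaustion genes in microglia-like cells (0.0086) and immunosuppressive myeloid genes in glioma/OPC-like cells (0.041). Leave-one-out counts of called lists were 6 to 12 in microglia-like, 3 to 10 in T cell-like and 6 to 11 in pericyte/smooth muscle-like cells, and 11 in T cell-like cells without both doubted libraries. Leave-one-out medians of type I interferon genes were 0.08 to 1.88 in glioma/OPC-like, 0.06 to 0.79 in microglia-like and −0.15 to 0.30 in T cell-like cells. In T cell-like cells the median was 0.45 without both doubted libraries and −0.17 with at least 500 genes and at most 10% mitochondrial UMIs.

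List calls were also lost under other settings. Without both doubted libraries these were hypoxia (−0.23), oligodendrocyte lineage (0.02), mesenchymal (−0.45), extracellular matrix (−0.25) and mitochondrial genes (0.19) in glioma/OPC-like cells, chemokines (−0.45) and disease-associated genes (0.01) in microglia-like cells, chemokines (0.53), homeostatic (0.23), hypoxia (−0.03) and mesenchymal genes (−0.17) in monocyte/macrophage-like cells and immediate early genes (0.55) in T cell-like cells. With the replicate block they were mesenchymal genes (−0.47) in glioma/OPC-like, MHC class II (0.26) and immediate early genes (0.31) in microglia-like and MHC class I genes (0.29) in T cell-like cells. With the stricter filter they were oligodendrocyte lineage (0.18), mesenchymal (−0.71) and mitochondrial genes (0.03) in glioma/OPC-like, apoptosis (0.47), mesenchymal (−1.48) and extracellular matrix genes (−1.08) in monocyte/macrophage-like, MHC class I genes (0.21) in T cell-like and mitochondrial genes (−0.36) in pericyte/smooth muscle-like cells. Of these, all but apoptosis and the pericyte/smooth muscle-like call were also lost by leaving out the same library alone. With top doublets removed they were oligodendrocyte lineage (−0.02), mesenchymal (−0.65) and extracellular matrix genes (−0.45) in glioma/OPC-like, hypoxia (−0.26) and mesenchymal genes (−0.53) in monocyte/macrophage-like and MHC class I (0.32) and immediate early genes (0.46) in T cell-like cells. Sums of at least 50 cells leave out KO replicate 1 in glioma/OPC-like and monocyte/macrophage-like cells and lost the same calls as that omission. Cluster settings ended MHC class II in microglia-like cells (0.82 with all variable genes, 0.70 at resolution 2). In monocyte/macrophage-like cells they ended homeostatic genes (0.27 at resolution 0.5, 0.21 at 2, 0.22 merged), mitochondrial genes (−0.16 at resolution 0.5, −0.10 merged), chemokines (0.52 at resolution 2) and extracellular matrix genes (−0.86 at resolution 2, also lost without KO replicate 1 alone).

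Phagocytosis and complement genes in glioma/OPC-like cells were at −0.18 with that stricter filter, −0.07 with doublets kept, −0.43 with clusters from all variable genes and −0.11 at Leiden resolution 0.5. Chemokines in monocyte/macrophage-like cells were at −0.30 at Leiden resolution 0.5 and −0.57 with macrophages merged. Leave-one-out medians ran from −0.08 to 2.04 (immunosuppressive myeloid genes, glioma/OPC-like), −0.10 to 1.33 (type II interferon, microglia-like), −0.21 to 1.23 (MHC class II, microglia-like), −0.63 to 2.24 (type II interferon, pericyte/smooth muscle-like) and −1.78 to 0.22 (hypoxia, pericyte/smooth muscle-like).

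The Adar log2 fold change in T cell-like cells was 0.09 without both doubted libraries and −0.46 to 0.07 leave-one-out, and −0.10 to 0.70 over all cells. The microglia-like share changed by 0.17 (log2) at Leiden resolution 0.5, by 0.51 without both doubted libraries and by −0.83 to 0.42 leave-one-out, and the pericyte/smooth muscle-like share by −0.32 to 0.83. The interferon difference was −1.05 to 0.44 for glioma/OPC-like against monocyte/macrophage-like and −0.05 to 1.03 for glioma/OPC-like against microglia-like cells.

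Named genes that changed sign, by setting, were as follows. With limma-voom: Ifitm3 −0.45 (glioma/OPC-like), Il7r −0.07 and Apoe −0.88 (T cell-like). Without both doubted libraries: Lgals1 0.10 and Hmox1 1.06 (glioma/OPC-like), Ccl5 −1.50 and Ctsd 0.08 (microglia-like), Apoe −0.26 (monocyte/macrophage-like) and Il7r −0.18 (T cell-like). With top doublets removed: Postn 0.13 (glioma/OPC-like) and Apoe −0.94 (T cell-like). With clusters from all variable genes: C1qa −0.77 (glioma/OPC-like) and Ccl5 −0.59 (microglia-like). With the stricter filter: Cebpb −0.70 and Casp4 −0.18 (monocyte/macrophage-like) and Ctla4 −0.13 (T cell-like). In monocyte/macrophage-like cells, Leiden resolution 0.5 gave Cebpb −0.15, Apoe −0.14 and Hsp90ab1 −0.12, resolution 2 gave Cebpb −0.32 and Apoe −0.18, merging gave Cebpb −0.13, Apoe −0.08 and Hsp90ab1 −0.13, and sums of at least 50 cells gave Apoe −0.09.

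Leave-one-out ranges of named genes that changed sign were, in glioma/OPC-like cells, Isg15 −0.14 to 2.17, Ifitm3 −0.67 to 1.04, Atf4 −0.10 to 0.43, Gapdh −1.26 to 0.08, Hmox1 −2.31 to 0.63, Lhfpl3 −0.26 to 0.26, Apoe −0.78 to 0.28, Sparc −0.83 to 0.10 and Postn −0.48 to 0.35. In microglia-like cells they were Cd74 −0.36 to 3.83, Ifih1 −0.11 to 1.05 and Ccl5 −1.01 to 3.09, and in monocyte/macrophage-like cells Cxcl2 −0.94 to 0.29 and Apoe −0.09 to 0.71. T cell-like cells gave Tox −0.07 to 0.92, Ctla4 −0.07 to 0.58, Il7r −0.41 to 0.60 and Apoe −2.56 to 1.20, and pericyte/smooth muscle-like cells Ifitm3 −0.24 to 0.68, Cxcl10 −1.39 to 2.06, B2m −0.21 to 1.39 and Gapdh −2.0 to 0.21.

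Replicate numbers did not pair the libraries: after the group means were removed, same-numbered libraries correlated at r = −0.11, 0.38 and −0.13 over all cells. With the number as a block, edgeR called 0 genes in the 4 classes with 6 libraries and limma 0 for the 3 differences between classes, and 9, 9, 13 and 6 lists were called in glioma/OPC-like, microglia-like, monocyte/macrophage-like and T cell-like cells. The block gave type I interferon medians of 1.19, 0.46, 1.05 and −0.03 in the same order, Adar 0.78, 0.57, 0.58 and −0.23 with 0.30 over all cells, and Apoe −0.89 in T cell-like cells. It gave T cell-like and glioma/OPC-like shares of 2.02 and −0.60. The block could not be fitted in pericyte/smooth muscle-like cells (1 shared number), nor sums of at least 50 cells in T cell-like and pericyte/smooth muscle-like cells, nor, in the latter, the removal of top doublets or of both doubted libraries.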

Other observations

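In this part, the tests of RNA from other cells, of deletion against tamoxifen, of interferon in glioma/OPC-like cells, host cells and 3′ tags for Adar, and of sex-linked transcripts in KO replicate 1 were chosen after the result was seen. The first pattern weighed was the higher type I interferon list in monocyte/macrophage-like cells of KO-labelled libraries. A shift between clusters was argued against as the whole cause, since the median was 1.12 within cluster 2 and 1.09 within cluster 27. Thinning every class sum to 165043 UMIs gave 1.07, but thinning keeps the expected proportions of genes, so it cannot decide on depth. Median UMIs per cell were not equalised. They were 5821.5, 8295.5 and 14216.5 in KO replicates 1, 2 and 3 and 3020.5, 2264.5 and 3298 in WT replicates 1, 2 and 3. The cluster values rest on fewer libraries, 2 against 2 and 2 against 3, and leave out KO replicate 1, which had 10 and 7 cells there and whose list level lay inside the WT range. RNA from other cells would be shared by all classes of a library, yet T cell-like cells had a median of 0.01, a value that turned to 0.30 without KO replicate 1 and so decides nothing. Deletion of Adar1 and tamoxifen itself cannot be told apart, because all KO-labelled and no WT-labelled libraries received tamoxifen; 2 of the 3 KO-labelled libraries lay above every WT-labelled one.

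The second pattern was that Adar transcripts were not lower in KO-labelled libraries. Host cells in the glioma/OPC-like class were argued against as the whole source in KO replicates 2 and 3. From the lowest sex-linked level of any other class, the host share was at most 12.7% and 40.3%, which at the highest Adar level elsewhere would bring 10.5 and 44.9 unscaled CPM, where the class held 42.4 and 111.6 (lower 95% counting limits 33.7 and 88.6). Host cells stay open in KO replicate 1 (46.4 CPM), whose host share cannot be read, and so do 3′ tags that may lie outside the deleted exons, which the labels do not give (Adar at 0.83, log2). The share of tumour cells that had lost Adar1 was not measured. Transcription of Adar driven by interferon stays open as well. Over the 6 libraries, Adar and the type I interferon list gave r = 0.78 in glioma/OPC-like cells (permutation p = 0.068, Spearman rho 0.54), too few libraries to decide. In microglia-like cells r was 0.9 (permutation p = 0.014), but the labels place the floxed gene in the injected tumour cells, so this decides nothing for them.

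The third pattern was that KO replicate 1 held both Xist (250.8 CPM) and Y-linked transcripts (238 CPM). Only 5 cells had both, where 30.5 were expected if they fell on cells independently (Fisher's exact p = 3.1e-13), with 73 cells carrying Xist alone and 126 Y-linked transcripts alone. Free RNA would fall on cells independently, so the expected 30.5 argued against it, and swapped indices were argued against by at most 4 of 798 barcodes shared with another library. Cells of more than 1 animal may therefore be in the library. Outside the glioma/OPC-like class 72 cells carried Xist alone and 115 Y-linked transcripts alone, so tumour cells of another sex than the host are not enough, and no biological explanation was tested. Sex-linked transcripts also differed within both groups. Xist prevailed in KO replicate 3 (969.3 CPM) and WT replicate 2 (1039 CPM). Y-linked transcripts prevailed in KO replicate 2 (296.7 CPM), WT replicate 1 (496.3 CPM) and WT replicate 3 (226.3 CPM). Sex was not a covariate in any fit.

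A hypothesis came from Fkbp5 and Tsc22d3, which glucocorticoids induce and which had positive log2 fold changes in monocyte/macrophage-like cells. A glucocorticoid response may explain them, and a list of its target genes was tested with limma's camera. The list was written before its values were computed, though its member Mt1 had been seen. Medians were 0.47 (microglia-like), 0.17 (monocyte/macrophage-like), −0.18 (glioma/OPC-like) and 0.36 (T cell-like). The camera test did not pass in any of these 4 classes, which leaves the hypothesis open.

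Splitting the 6 libraries into groups of 3 gives 10 splits, the real one included, too few for a share under 0.05. The numbers of splits below count the real one. For genes called by edgeR, the real count was 0 in glioma/OPC-like, microglia-like, monocyte/macrophage-like and T cell-like cells. All 10 splits must then give as many, so this count decides nothing. The highest other counts were 1, 2, 1 and 2. At an unadjusted p under 0.05 the real split gave 488, 1059, 1056 and 159 genes, and the highest other counts were 1114, 1259, 599 and 459. DESeq2 called 16, 32, 159 and 0 for the real split. For lists called by camera, the real counts were 10, 11, 13 and 6, the highest other counts 17, 13, 10 and 9, and 8, 4, 1 and 7 splits gave as many. For the type I interferon median, the real values were 1.34, 0.49, 1.07 and 0.01, the highest other sizes 1.98, 1.07, 0.98 and 0.64, and 7, 5, 1 and 10 splits gave one as large. For the 3 differences between classes the real and the highest other counts of limma were 0 in all 10 splits, which cannot set the real split apart (452, 450 and 693 genes at an unadjusted p under 0.05).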
